A study of Mus musculus with 24 samples.

How the data were processed

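Gene expression was measured by RNA sequencing in 24 libraries of mouse bone-marrow-derived macrophages. The libraries came from 6 mice, 3 with intact liver X receptors and 3 labelled as double knockouts of LXRα and LXRβ (DKO), each with 4 treatments. Per the labels' protocols, marrow cells were grown in medium conditioned by L929 cells, the medium was renewed after 4 days, and vehicle, KLA at 100 ng/ml or GW3965 at 1 µM was given on day 5 for 17 hours. AcLDL was given at 50 µg/ml, and its duration is not given in the sources used here. RNA was isolated with Qiagen RNeasy columns, and 500 ng of it entered a stranded total RNA kit (SMARTer, Clontech), per the labels' protocols. Sequencing was single-end with 50 bp reads, per the series' design text.

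The authors deposited 3 tables, 1 per treatment with its vehicle libraries, each holding a value per gene and library and the authors' own test of the difference in response between genotypes. Per the submitters' processing notes the tools were kallisto and DESeq2 and the genome build was GRCm38. Their versions, the gene annotation and the strand setting of the counting are not given in the sources used here. The deposited values are a signal of normalized counts per gene, that is, whole gene counts divided by 1 size factor per library. This was checked on the values: the smallest step in each library gave back whole reads for 100% of values in every library, within 0.01 read. The vehicle columns were identical in the 3 tables, so 1 normalization covers all 24 libraries. The authors' deposited score is the Wald statistic of their DESeq2 fit, the log2 fold change divided by its standard error, and was not used here. The authors' deposited log2 fold changes and adjusted p-values were used only to set their calls beside those made here. Of 47372 genes in the tables, 12616 were at 0 in every library, and 558 entries share a symbol with another entry.

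Gene coordinates are those of the GRCm38 annotation at hand (GENCODE M21), which holds 46648 of the 47372 gene identifiers. Of these, 42455 (91.0%) had the same start and end as in the deposited tables. Because the strand setting of the counting is unknown, the values of genes that overlap on opposite strands are uncertain, as are those of close gene families. Of the genes named, Cyp51, Fdft1, Srebf1, Ciita, Itgav, Il1a, Slco2b1, Mid1, Gramd1b and Stab1 share 84 (Gramd1b) to 951 (Mid1) exon bases with an expressed gene on the opposite strand.

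The main test was limma-trend on log2(value + 1), with 4 group means (vehicle and treated in both genotypes, 12 libraries) and 1 shared spread. Genes entered when at least 3 of the 12 libraries reached 10 normalized counts. P-values were adjusted by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05. A log2 fold change is on the log2(value + 1) scale, which understates the change of low genes. Because the deposited unit is not raw counts, edgeR's quasi-likelihood test and DESeq2 on the recovered reads were run only as alternatives. The difference between DKO and LXR-positive vehicle libraries was fitted with the GW3965 libraries, and responses were compared between genotypes by an interaction contrast.

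The series' design text gives 6 mice and 4 treatments, so libraries of 1 genotype with the same number come from the same mouse. Deviations of same-numbered libraries from their group means correlated at a median r of 0.248 over 10732 genes (18 pairs of groups, r from -0.005 to 0.484, 17 of them over 0.1). In 17 of the 18 the own number correlated best. Fits with the mouse as a block were therefore run beside the main unblocked test. No label used here pairs mice across genotypes by number. Deviations of same-numbered vehicle libraries correlated across genotypes at r = -0.28, -0.101 and 0.276 for numbers 1, 2 and 3. The mean level of cell cycle genes was highest in number 2 and lowest in number 3 in the vehicle and KLA groups of both genotypes. A batch shared by number was not tested and stays open.

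Before the data were examined, the groups, the tests, 23 gene lists, the rule for named genes and most alternatives were fixed. The lists covered LXR target genes, cholesterol synthesis and uptake, fatty acid synthesis and desaturation, lipid uptake with PPAR targets, inflammatory mediators, interferon-stimulated genes, MHC class II, alternative activation, efferocytosis, lysosome, cell cycle, NRF2 targets, the unfolded protein response, and glycolysis with hypoxia. Others marked macrophages, neutrophils and their precursors, dendritic cells, lymphocytes, stromal cells, erythroid cells and megakaryocytes, mast cells with basophils and eosinophils, and osteoclasts, and the last held mitochondrial and structural RNAs. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over the 23 lists, with an estimated correlation and with fry beside it. Camera with the mouse block was run at the preset correlation only. fry tests whether a list's genes move, on balance, 1 way. Entries on patch scaffolds were left out of the lists where the same symbol was tested on a chromosome, a choice made after the list results were seen. The macrophage list counts 11 entries for 10 genes, because Itgam has 2 identifiers.

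The text names Nr1h3, Nr1h2, Abca1, Abcg1, Srebf1 and Mylip always. It also names, among called genes with non-overlapping groups and a mean of at least 100 normalized counts, the 5 with the largest positive and the 5 with the largest negative log2 fold change, leaving out pseudogenes and genes known only by a model or clone number. Of each list it names up to 3 called members with the largest change, lists with most called members first. Not every gene that the rule covers is reported here, and counts over named genes include all that it covers. Genes outside this rule, and sets of genes listed in full because they were called, are marked as chosen after their values were seen.

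Alternatives were median-of-ratios rescaling, other pseudocounts (0.25 and 8), quantile normalization, no filter, a filter at 50, a 2-fold threshold, only the groups compared, the mouse block, the KLA or AcLDL libraries in place of the GW3965 libraries at baseline and leaving out each library in turn. Both count tests and reads thinned at random to the lowest library total (6448579 reads) were added after the values were seen.

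The test was checked on simulated counts. For GW3965 against vehicle in LXR-positive cells (15841 simulated genes in the fit), it recovered 52.9%, 91.2% and 93.9% of genes raised 2-, 4- and 8-fold, and 28.1%, 71.0% and 87.9% of those lowered as much. For the GW3965 response between genotypes (15821 genes) it recovered 18.8%, 39.4% and 84.4% of differences of these sizes below 0, and 14.7%, 82.4% and 81.8% of those above 0. These simulations also called 11 and 10 unchanged genes, 7.28% and 8.62% of their calls. A simulation of the first comparison with no change gave 0 calls among 15832 genes.

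Recovered totals ran from 6448579 to 27189081 reads per library. In a group at 0 in every library, 3 reads per library were taken as the floor, which covers counting error only. Software was R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.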

Results

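RNA sequencing measured gene expression in macrophages grown from the bone marrow of 6 C57BL/6J mice. Of these, 3 carried intact liver X receptors (LXR-positive), and the other 3 gave libraries labelled DKO, for double knockout of LXRα and LXRβ. Liver X receptors are nuclear receptors that bind oxidized cholesterol derivatives and switch on genes of cholesterol export and fatty acid synthesis. Cells of each mouse received vehicle, KLA (Kdo2-lipid A, the part of bacterial lipopolysaccharide that activates TLR4), GW3965 (a synthetic LXR agonist) or AcLDL (acetylated low-density lipoprotein, which scavenger receptors take up and which loads macrophages with cholesterol). That made 8 groups of 3 libraries, 24 in all, and the series title names LXR-dependent expression as its subject. Values are the authors' normalized counts, and groups are given as mean ± SD with n = 3 mice.

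Depth differed between genotypes. By group, LXR-positive libraries held 10540385 to 17348717 reads (vehicle), 8856391 to 10179626 (KLA), 6448579 to 8793205 (GW3965) and 8280899 to 8723714 (AcLDL). DKO libraries held 20659071 to 27189081, 14084070 to 21644900, 9705391 to 17671480 and 15263971 to 18739975 reads in the same order. Genotype and depth can therefore not be separated by grouping alone, and the mean number of genes detected was 21761 in LXR-positive and 24588 in DKO libraries. Transcripts of the mitochondrial chromosome took 15.9 ± 3.29% of reads in LXR-positive and 13.5 ± 2.47% in DKO libraries. These 2 values are mean ± SD over the 12 libraries of a genotype with all treatments pooled, so their spread is not that between mice. The KLA groups, which they include, had lower shares (11.9 ± 3.32% and 10.2 ± 2.10%, n = 3). Libraries of a group correlated at r = 0.9446 to 0.9805 across genes, which are not independent replicates.

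The targeted genes came first. Nr1h2, which encodes LXRβ (ENSMUSG00000060601, GRCm38 chromosome 7, 44549616 to 44553951), stood at 582 ± 66.0 normalized counts in LXR-positive and 329 ± 64.0 in DKO vehicle libraries. All 12 DKO libraries (275 to 399) lay below the lowest LXR-positive library (438), although the vehicle difference did not pass the test (log2 difference -0.83 ± 0.18 SE, limma adjusted p = 0.10). The 12 libraries of a genotype come from 3 mice, so they are not independent values. Nr1h3, which encodes LXRα (ENSMUSG00000002108, chromosome 2, 91184061 to 91202834), stood at 135 ± 35.8 and 181 ± 5.43 in vehicle libraries (0.45 ± 0.25, adjusted p = 0.49). These totals sum reads over the whole gene. The deleted exons are not given in the sources used here, so the totals do not check the DKO labels.

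GW3965 raised LXR target genes and fatty acid synthesis genes in LXR-positive macrophages. Abca1, the transporter that hands cellular cholesterol to apolipoprotein A-I (chromosome 4), rose from 8684 ± 477 to 38559 ± 3148 normalized counts, and Abcg1, which exports cholesterol to high-density lipoprotein (chromosome 17, 31057698 to 31115777), from 1929 ± 94.6 to 12605 ± 631. Mylip, a ubiquitin ligase gene, rose from 1235 ± 161 to 4288 ± 605. Srebf1, the transcription factor of fatty acid synthesis genes, rose from 258 ± 32.4 to 1914 ± 144, and Scd2, a fatty acid desaturase (chromosome 19, 44293676 to 44306864), from 238 ± 6.51 to 12353 ± 600.0. In limma these log2 fold changes were 2.15 ± 0.10 SE for Abca1 (adjusted p = 4.8e-07), 2.71 ± 0.11 for Abcg1 (1.8e-07), 1.79 ± 0.12 for Mylip (1.7e-05), 2.89 ± 0.15 for Srebf1 (8.2e-07) and 5.69 ± 0.24 for Scd2 (1.8e-07).

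**Figure D1:**
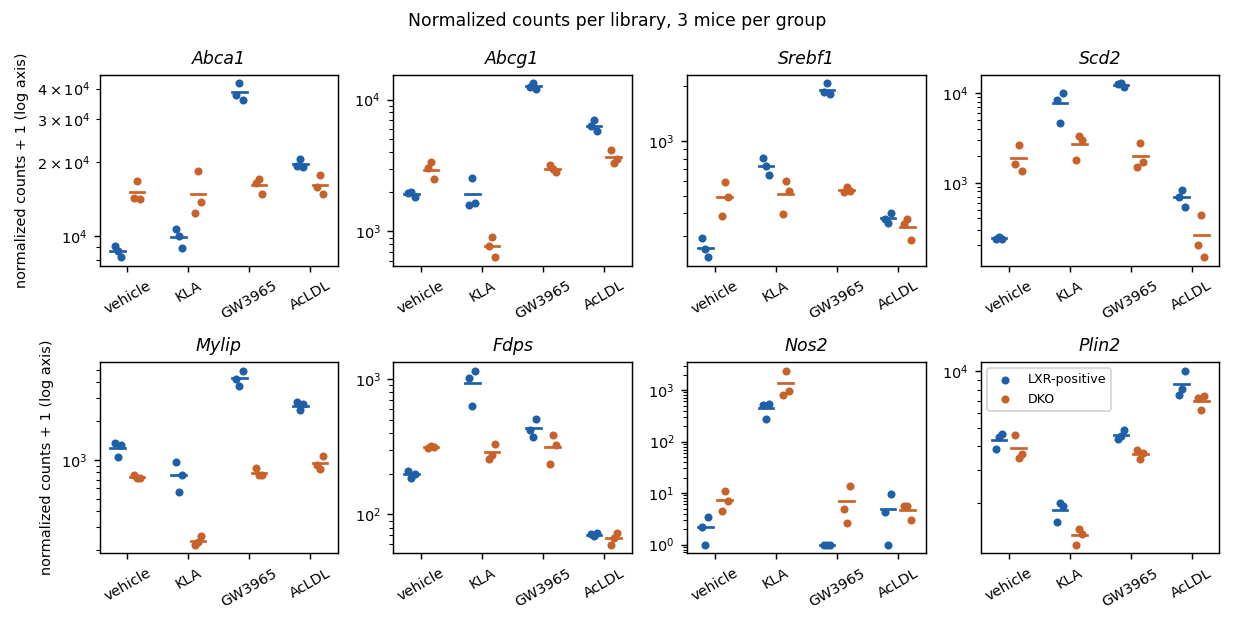
Normalized counts (log axis) of 8 genes in the 8 groups, with a point per library and a bar at the mean of 3. Abca1 and Abcg1 rose with GW3965 and AcLDL in LXR-positive libraries (Abca1 8684 with vehicle, 38559 with GW3965 and 19658 with AcLDL), Plin2 rose with AcLDL in both genotypes (from 4343 to 8571 and from 3909 to 6975), and Nos2 rose with KLA in both (to 444 and 1374).

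Of 22 tested LXR target genes, 13 rose and 0 fell with GW3965 in LXR-positive cells, or 15 when adjusted over the list alone (median log2 fold change 1.31, camera adjusted p = 3.2e-48, adjusted p = 1.9e-05 with an estimated correlation). Fatty acid synthesis genes, which share 7 genes with that list, rose in 11 of 15 cases (13 adjusted over the list alone; camera adjusted p = 3.6e-47, 0.0014 with an estimated correlation). They included Scd1, another desaturase (log2 fold change 6.79 ± 0.56), the desaturase Fads2 (3.60 ± 0.42) and fatty acid synthase, Fasn (2.88 ± 0.24). Among 24 genes of cholesterol synthesis and uptake, 3 rose, among them Insig1, which retains SREBP proteins in the endoplasmic reticulum (1.38 ± 0.16), and Fdps, farnesyl diphosphate synthase (1.12 ± 0.17). Adjusted over the list alone, 19 of these 24 passed (camera adjusted p = 8.5e-32, 0.013 with an estimated correlation). Mertk, a receptor for apoptotic cells, was the member of 16 efferocytosis genes that rose (0.77 ± 0.11, adjusted p = 0.0064), and Il1a, the cytokine interleukin-1α, the member of 22 inflammatory mediators (2.45 ± 0.40, adjusted p = 0.022). Rgs3, a regulator of G protein signalling, fell by 0.97 on the log2 scale (adjusted p = 0.039). None of the 26 interferon-stimulated genes passed in limma, with a median of -0.39 (camera adjusted p = 3.5e-08, adjusted p = 0.56 with an estimated correlation). Their fry adjusted p was 0.53. In the 18 lists without a called member, these included, camera called interferon-stimulated genes alone. Nr1h3 and Nr1h2 had log2 fold changes of 0.10 ± 0.25 and -0.13 ± 0.18.

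In total 43 of 16116 tested genes changed with GW3965 in LXR-positive macrophages, 40 higher and 3 lower, and DESeq2 on the recovered reads called 87. With the mouse as a block 52 genes were called, Il1a lost its call (adjusted p = 0.0915), and 4 more lists were called in limma's camera: cell cycle (lower, adjusted p = 0.0021), glycolysis (lower, 0.015), osteoclast (lower, 0.018) and erythroid and megakaryocyte (higher, 0.018). Of the 14 named genes called, 3 lost the call without single libraries: Rgs3 without any of the 6 (adjusted p from 0.064 to 0.19), Fdps without any vehicle library or GW3965 library 1 or 3 (0.052 to 0.069), and Il1a without vehicle library 1 or 2 or any GW3965 library (0.064 to 0.11). Quantile normalization, no filter and thinned reads also ended the calls of Rgs3 (0.062 to 0.12) and Il1a (0.0705 to 0.16), and edgeR that of Rgs3 (0.064). With only the 6 libraries compared, Rgs3 (0.29), Il1a (0.088), Fdps and Mertk (0.051 each) were not called. Scd1, Scd2 and Scd4 are close copies, so how reads were divided between them is uncertain.

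In DKO macrophages the genes that rose in LXR-positive cells did not pass the test with GW3965. Abca1 stood at 15100.5 ± 1414 with vehicle and 16146 ± 1110.2 with GW3965, Abcg1 at 2945 ± 429 and 2997 ± 178, and Scd2 at 1869 ± 687 and 1986 ± 677. Mylip (730.4 ± 24.4 and 794 ± 61.8) and Srebf1 (489.5 ± 103 and 537 ± 20.2) moved by less than the test could tell from the spread (log2 fold changes 0.12 ± 0.12 and 0.15 ± 0.15). A single gene passed in limma, Zfp708, a zinc finger gene, named because it was the only call and chosen after its value was seen. It had 0 reads in the DKO GW3965 libraries, at least 8.27-fold lower than with vehicle, and shares 2537 of its 2633 exon bases with another gene model. limma found 940 genes at an unadjusted p under 0.05, edgeR called 0 genes, DESeq2 26 (12 higher, 14 lower), and limma with the mouse block 0. Leaving out DKO vehicle library 2 or 3 or GW3965 library 1 or 2 gave 0 calls in limma, leaving out DKO vehicle library 1 gave 1 call and leaving out GW3965 library 3 gave 2, none of them Zfp708. No list was called in DKO cells (22 LXR targets, camera adjusted p = 0.17), and an estimated correlation and fry gave 0 as well. With the mouse block camera called 6: stromal (adjusted p = 1.1e-04, median 0.97), efferocytosis (0.0012), neutrophil (0.0012), inflammatory (0.014) and fatty acid genes (0.020) higher, and MHC class II lower (0.0072).

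Tested directly, the GW3965 response differed between genotypes for 19 of 16116 genes, 18 lower in DKO and 1 higher. Among the genes named by rule the largest differences, DKO minus LXR-positive, were -6.48 ± 0.79 SE for Scd1 (limma adjusted p = 0.0052), -5.59 ± 0.34 for Scd2 (1.2e-05), -3.68 ± 0.60 for Fads2 (0.044), -2.86 ± 0.34 for Fasn (0.0043) and -2.74 ± 0.21 for Srebf1 (8.0e-05). Abcg1 (-2.67 ± 0.15), Abca1 (-2.05 ± 0.14), Mylip (-1.68 ± 0.18) and Insig1 (-1.52 ± 0.23) also passed. Of the 22 LXR targets 8 were called lower (14 adjusted over the list alone; camera adjusted p = 1.9e-36, 5.6e-05 with an estimated correlation). Fatty acid genes gave 6 of 15 (11; adjusted p = 0.0046 with an estimated correlation) and cholesterol genes 1 of 24 (12; 0.040). All 26 interferon-stimulated genes had a positive difference but 0 passed in limma (median 0.38, camera adjusted p = 3.9e-05, adjusted p = 0.76 with an estimated correlation). The remaining lists were not called without the block. With it camera also called inflammatory (adjusted p = 0.0034), cell cycle (0.013), glycolysis (0.013), neutrophil (0.040), stromal (5.0e-04) and osteoclast genes (0.0077), all above 0, and 2 of the 19 calls, of genes outside the naming rule, ended. Without the block, an estimated correlation called 3 lists, LXR targets, fatty acid and cholesterol genes, and none of those that the block added. Leaving out any library but DKO vehicle 3 or GW3965 2 ended the call of Fads2 (adjusted p 0.098 to 0.18), and Insig1 lost its call without LXR-positive vehicle 3, any LXR-positive GW3965 library, DKO vehicle 2 or DKO GW3965 1 or 3 (0.063 to 0.090). The call of Fads2 also ended with a pseudocount of 8, in edgeR and with thinned reads (0.051 to 0.20). DESeq2 called 55 genes.

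AcLDL lowered genes of cholesterol synthesis and uptake in both genotypes. Fdps fell by 1.48 on the log2 scale in LXR-positive macrophages (limma adjusted p = 1.7e-04) and fell by 2.24 in DKO macrophages (6.1e-06, 313 ± 5.83 to 65.5 ± 6.59 normalized counts). Plin2, a protein that coats lipid droplets, rose in both (0.97 ± 0.14 and 0.84 ± 0.14), as did Angptl4, an inhibitor of lipoprotein lipase and PPAR target (1.81 ± 0.22 and 1.77 ± 0.22). Abcg1 and Abca1 rose in LXR-positive cells, to 6350.2 ± 561 and 19658 ± 828 normalized counts (log2 fold changes 1.72 ± 0.12, adjusted p = 6.0e-05, and 1.18 ± 0.10, 1.7e-04). In DKO cells they had log2 fold changes of 0.32 ± 0.12 and 0.10 ± 0.10, which did not pass.

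Of 24 cholesterol genes, 9 fell with AcLDL in LXR-positive cells (14 adjusted over the list alone; median -0.70, camera adjusted p = 5.8e-20, 0.023 with an estimated correlation) and 13 in DKO cells (20; median -1.43, 8.6e-60, 0.0011). Idi1, an enzyme of isoprenoid synthesis (-1.40 ± 0.21 and -2.37 ± 0.21), and Stard4, a cholesterol carrier (-1.25 ± 0.20 and -1.74 ± 0.20), fell in both. LXR targets rose in 4 of 22 cases in LXR-positive cells (8 adjusted over the list alone; camera adjusted p = 6.2e-10, 0.0054 with an estimated correlation), Mylip among them (1.10 ± 0.12). In DKO cells 1 of the 22 fell, the desaturase Scd2 (camera adjusted p = 0.066, 0.020 with the mouse block). Srebf1 had log2 fold changes of 0.54 ± 0.16 and -0.54 ± 0.16, neither called. Fatty acid genes gave 0 calls in LXR-positive cells in limma (5 higher adjusted over the list alone; camera adjusted p = 0.043, adjusted p = 0.49 with an estimated correlation) and 1 lower in DKO cells (10; 3.4e-13, 0.043). Lipid uptake and PPAR target genes rose in 2 of 18 cases in each genotype, Plin2 and Angptl4 (6 higher adjusted over the list alone in each). Camera gave adjusted p = 0.0014 and 1.9e-05, or adjusted p = 0.11 and 0.043 with an estimated correlation. Itgav, the integrin αV chain (1.08 ± 0.18, adjusted p = 0.042), was the efferocytosis member that rose in LXR-positive cells, and Pf4, a chemokine of megakaryocytes (1.29 ± 0.19, adjusted p = 0.024), the erythroid and megakaryocyte member.

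Interferon-stimulated genes had negative log2 fold changes with AcLDL in all 26 cases in each genotype (medians -1.01 and -0.49), but 0 of 26 passed in limma over all genes. In LXR-positive cells 26 of 26 were lower when adjusted over the list alone, and 11 were called lower with the mouse block. Camera gave adjusted p = 2.4e-24 and 3.1e-12, which became adjusted p = 0.11 and 0.29 with an estimated correlation. Of 22 inflammatory mediators 0 were called in limma (5 lower adjusted over the list alone in LXR-positive cells; medians -0.54 and -0.11, camera adjusted p = 2.8e-05 and 0.048, adjusted p = 0.11 and 0.44 with an estimated correlation). Cell cycle genes lay above 0 in 22 and 23 of 23 cases (medians 0.69 and 0.44) with 0 called in limma, and 6 called with the block in LXR-positive cells. Their camera adjusted p was 2.7e-04 and 2.2e-04, or adjusted p = 0.56 and 0.65 with an estimated correlation. Macrophage identity genes had medians of -0.32 and -0.29 (0 of 11 called in limma in each; camera adjusted p = 0.011 and 0.027, adjusted p = 0.17 and 0.26 with an estimated correlation). MHC class II genes (medians -0.35 and -0.39) were called in camera with the mouse block in LXR-positive (3.0e-05) and DKO cells (4.8e-07), and not without it (0.13 and 0.065).

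AcLDL changed 36 of 16026 tested genes in LXR-positive macrophages (16 higher, 20 lower) and 20 in DKO macrophages (2 higher, 18 lower), 11 of them called in both and all 11 in the same direction. With the mouse block the counts were 247 (86 higher, 161 lower) and 38 (5 higher, 33 lower), edgeR called 20 and 18, and DESeq2 285 and 82. The LXR-positive count was 10 without vehicle library 1, 11 without vehicle 3, 16 without AcLDL 1 or 3 and 22 without AcLDL 2. Among named genes, calls ended for Itgav without any of the 6 libraries (adjusted p 0.10 to 0.17), Pf4 without any but vehicle 2 (0.065 to 0.087), Stard4 without any but AcLDL 2 (0.061 to 0.12), Idi1 without vehicle 1 or 3 or AcLDL 1 or 3 (0.066 to 0.11) and Plin2 without vehicle 1 or 3 or AcLDL 3 (0.060 to 0.087). Plin2 in DKO cells lost its call without any library but vehicle 1 (0.076 to 0.26). Other settings ended the calls of Plin2 in DKO cells (no filter, edgeR, thinned reads and only the 6 libraries compared, 0.052 to 0.20) and of Itgav (quantile normalization, no filter and edgeR, 0.051 to 0.072). With only the 6 libraries compared Angptl4, Plin2, Pf4, Idi1 and Stard4 were not called in LXR-positive cells (0.052 to 0.098).

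The AcLDL response differed between genotypes for 4 of 16026 genes. Scd2 (DKO minus LXR-positive -4.43 ± 0.49 SE, limma adjusted p = 0.0092), Abcg1 (-1.40 ± 0.17, 0.021) and Abca1 (-1.08 ± 0.14, 0.021) responded lower in DKO cells. Pole2, a subunit of DNA polymerase ε chosen after its value was seen, had 0 reads with AcLDL in LXR-positive cells, at least 7.30-fold lower than with vehicle. Of 22 LXR targets 3 were called lower (11 adjusted over the list alone; camera adjusted p = 2.1e-18, 5.3e-04 with an estimated correlation). Fatty acid genes gave 1 of 15 (6 adjusted over the list alone; 0.019 with an estimated correlation). Of 24 cholesterol genes 0 passed in limma (9 adjusted over the list alone; median -0.70, camera adjusted p = 2.1e-18, adjusted p = 0.019 with an estimated correlation). The 26 interferon-stimulated genes all had positive differences with 0 called in limma (median 0.47, camera adjusted p = 5.1e-09, adjusted p = 0.64 with an estimated correlation), and inflammatory mediators had a median of 0.32 (camera adjusted p = 0.026, adjusted p = 0.61 with an estimated correlation). Differences of response to GW3965, AcLDL and KLA share the same vehicle libraries, so they are not independent of each other. The mouse block, run at the preset correlation only, added cell cycle (adjusted p = 0.015), glycolysis (0.021) and neutrophil genes (0.0049) in camera. Calls were few and ended easily. The count was 1 without LXR-positive vehicle 1 or LXR-positive AcLDL 2, and 2 without LXR-positive vehicle 2, DKO vehicle 1 or 2, or DKO AcLDL 3. Abca1 lost its call without any library but DKO vehicle 3 or AcLDL 2 (adjusted p 0.055 to 0.11), Abcg1 without any but LXR-positive AcLDL 3, DKO vehicle 3 or DKO AcLDL 1 (0.056 to 0.11), and Scd2 without LXR-positive vehicle 1 or AcLDL 2 (0.052 and 0.054). No filter also ended the call of Abca1 (0.061), and edgeR with the block those of Abca1 (0.068) and Abcg1 (0.072). DESeq2 called 13 genes and edgeR 4, or 1 with the block.

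KLA raised genes of inflammatory mediators in both genotypes. Saa3, an acute-phase serum amyloid, rose from 189 ± 177 to 158402 ± 100505 normalized counts in LXR-positive and from 327 ± 245 to 244210.0 ± 80925 in DKO macrophages (log2 fold changes 9.90 ± 0.76 and 9.93 ± 0.76). Nos2, the inducible nitric oxide synthase, rose from 1.21 ± 1.22 to 444 ± 148 and from 6.45 ± 3.39 to 1374 ± 887. Ptges, which makes prostaglandin E2, rose by log2 fold changes of 7.87 ± 0.35 and 7.28 ± 0.35, and Il1a by 7.63 ± 0.43 and 6.47 ± 0.43. Saa1 had 0 reads in LXR-positive vehicle libraries and was at least 150-fold higher with KLA (479 ± 164). Among the genes that fell, Hpgd, which inactivates prostaglandins, had log2 fold changes of -7.42 and -7.07, Mrc1, the mannose receptor, of -4.91 and -4.38, and Pparg, a regulator of lipid storage, of -4.53 and -4.33. Slco2b1, an organic anion transporter, fell from 462 ± 101 to 0.934 ± 0.815 in LXR-positive and from 487 ± 52.4 to 1.80 ± 1.78 in DKO cells, and Samd4, an RNA-binding protein gene, from 337 ± 86.3 to 1.37 ± 1.31 and from 369 ± 162 to 10.2 ± 7.23. Bmp2, a growth factor, had log2 fold changes of -6.26 and -4.60.

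Inflammatory mediators rose in 22 of 26 cases and fell in 1 in each genotype (camera adjusted p = 9.7e-17 and 4.1e-17, 0.012 and 0.011 with an estimated correlation). Adjusted over the list alone, 23 and 22 rose. Interferon-stimulated genes rose in 18 of 26 cases in LXR-positive and 24 in DKO cells, with Isg15, a ubiquitin-like protein (2.34 ± 0.33 and 3.10 ± 0.33), and Zbp1, a sensor of nucleic acids (2.31 ± 0.29 and 3.01 ± 0.29), among them. Adjusted over the list alone, 18 and 26 passed. Their camera adjusted p was 3.1e-09 and 4.9e-17, or adjusted p = 0.32 and 0.19 with an estimated correlation. Glycolysis and hypoxia genes rose in 13 of 15 cases in both genotypes (13 in both adjusted over the list alone; camera adjusted p = 2.8e-10 and 1.4e-10, adjusted p = 0.17 and 0.19 with an estimated correlation). Pgk1 and Pfkl, enzymes of glycolysis, rose by 2.79 ± 0.16 and 2.67 ± 0.15 in LXR-positive and by 2.36 ± 0.16 and 2.20 ± 0.15 in DKO cells. Efferocytosis genes fell in 13 of 16 and 10 of 16 cases (14 and 11 adjusted over the list alone; camera adjusted p = 2.5e-08 and 1.2e-05, 0.0056 and 0.011 with an estimated correlation). Trem2, a lipid-sensing receptor, fell by 3.13 in both, Gas6, a ligand of Mertk, had log2 fold changes of -2.64 and -2.46, and Stab1, a scavenger receptor, of -1.90 and -1.52.

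MHC class II genes fell in 7 of 9 cases in LXR-positive and 4 of 9 in DKO cells (7 and 4 adjusted over the list alone; camera adjusted p = 2.1e-04 and 0.0075, adjusted p = 0.17 and 0.30 with an estimated correlation), with Ciita, their transcriptional activator, falling from 594 ± 147 to 61.1 ± 24.4 and from 452 ± 293 to 75.4 ± 5.02. Alternative activation genes fell in 6 of 9 and 5 of 9 cases while 1 and 2 rose, Arg1, arginase, among those that rose (5.17 ± 0.62 and 5.98 ± 0.62). Adjusted over the list alone, the same numbers passed. Camera gave adjusted p = 0.0035 and 0.023, or adjusted p = 0.16 and 0.19 with an estimated correlation. Lipid uptake and PPAR target genes fell in 8 of 18 cases and rose in 2 in LXR-positive cells, and fell in 6 and rose in 1 in DKO cells (8 and 7 lower adjusted over the list alone; camera adjusted p = 0.018 and 0.0075, adjusted p = 0.17 and 0.19 with an estimated correlation). Angptl4 fell from 76.8 ± 19.3 to 4.45 ± 3.09 and from 72.9 ± 11.4 to 1.70 ± 0.243. Neutrophil and granulocyte precursor markers fell in 9 of 11 and 5 of 11 cases (9 and 7 adjusted over the list alone; camera adjusted p = 2.8e-05 and 0.0016, adjusted p = 0.17 and 0.30 with an estimated correlation), with Mpo, myeloperoxidase, falling from 179 ± 34.8 to 8.70 ± 2.89 and from 457 ± 123 to 25.9 ± 5.41. Cell cycle genes fell in 10 of 23 cases and rose in 1 in DKO cells (13 and 1 adjusted over the list alone; camera adjusted p = 9.6e-05, adjusted p = 0.43 with an estimated correlation). In LXR-positive cells 1 rose, E2f1, a transcription factor of the cell cycle (0.64 ± 0.13), and camera called the list lower with the mouse block (adjusted p = 0.049) and not without it (0.29).

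Genes of cholesterol synthesis rose with KLA in LXR-positive cells, 23 of 24 (23 adjusted over the list alone; median 1.51, camera adjusted p = 3.4e-13, adjusted p = 0.18 with an estimated correlation), whereas 1 rose and 3 fell in DKO cells (1 and 2 adjusted over the list alone; median -0.15, camera adjusted p = 0.20). Mvd, which makes isopentenyl diphosphate, rose by 2.66 ± 0.30 in LXR-positive and 1.18 ± 0.30 in DKO cells. Acat2, acetyl-CoA acetyltransferase 2 (2.67 ± 0.36), and Hsd17b7, an enzyme of late cholesterol synthesis (2.34 ± 0.34), rose in LXR-positive cells and had log2 fold changes of 0.73 ± 0.36 and 0.32 ± 0.34 in DKO cells, which did not pass. Fatty acid genes rose in 13 of 15 cases in LXR-positive cells (14 adjusted over the list alone; camera adjusted p = 2.6e-08, adjusted p = 0.17 with an estimated correlation), and in DKO cells 1 rose and 1 fell (camera adjusted p = 0.83). Scd2 rose from 238 ± 6.51 to 7708 ± 2769, Srebf1 from 258 ± 32.4 to 728 ± 81.1. LXR targets went both ways, 8 higher and 7 lower of 22 in LXR-positive cells and 4 higher and 8 lower in DKO cells (10 and 7, and 4 and 9, adjusted over the list alone). Their camera adjusted p was 0.42 and 0.055, and 0.036 (lower) in DKO cells with the mouse block. Nr1h3 rose from 135 ± 35.8 to 895 ± 361 and from 181 ± 5.43 to 672 ± 72.4. Mylip had log2 fold changes of -0.72 and -1.64, and Abcg1 fell by 1.94 in DKO cells. Abca1 (0.18 ± 0.14 and -0.04 ± 0.14) and Nr1h2 (0.11 ± 0.21 and 0.06 ± 0.21) were not called.

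KLA changed 4566 of 15957 tested genes in LXR-positive macrophages (2584 higher, 1982 lower) and 4016 in DKO macrophages (2238 higher, 1778 lower), and 2091 and 1846 were called with a fold over 2. The mouse block gave 4789 and 4249. Both genotypes called 2965 genes, 2959 of them in the same direction. Of the named genes called, 7 of 61 in LXR-positive and 6 of 50 in DKO cells lost the call without at least 1 single library. Among them, Mvd in DKO cells lost it without DKO vehicle library 1 (adjusted p = 0.058). E2f1 in DKO cells lost it without DKO vehicle 3 or KLA 1 (limma adjusted p 0.05004 to 0.051) and with thinned reads (0.115).

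Tested directly, the KLA response differed between genotypes for 11 of 15957 genes, all lower in DKO cells. They included enzymes of cholesterol synthesis (Cyp51 -2.80 ± 0.33 SE, Idi1 -2.58 ± 0.31, Fdps -2.32 ± 0.27 and Fdft1 -2.05 ± 0.31), enzymes of fatty acid synthesis (Fads2 -4.88 ± 0.76, Scd2 -4.39 ± 0.44 and Acaca, the acetyl-CoA carboxylase that starts fatty acid synthesis, -1.35 ± 0.19) and Abcg1 (-1.90 ± 0.26). Their limma adjusted p ran from 0.0030 (Scd2) to 0.047 (Fads2). Of 24 cholesterol genes 5 were called lower, 22 adjusted over the list alone and 14 with the mouse block (median -1.71, camera adjusted p = 1.5e-46, 0.030 with an estimated correlation). Fatty acid genes gave 3 of 15 (13 adjusted over the list alone; 0.021 with an estimated correlation) and LXR targets 2 of 22 (8 lower and 1 higher; 0.017). Beside them, 22 of 23 cell cycle genes also had a negative difference (median -0.78, 0 called in limma, camera adjusted p = 8.1e-06, adjusted p = 0.57 with an estimated correlation), and their mean log2 level was 7.76 to 9.16 in the DKO vehicle libraries and 6.81 to 8.76 in the LXR-positive ones. Interferon-stimulated genes had positive differences in 25 of 26 cases (median 0.64, 0 called in limma, camera adjusted p = 5.7e-10, adjusted p = 0.40 with an estimated correlation). MHC class II genes (median 0.51, camera adjusted p = 0.024, adjusted p = 0.44 with an estimated correlation), macrophage identity genes (0.31, 0.046, 0.30 with an estimated correlation) and efferocytosis genes (0.20, 0.0046, 0.048) also lay above 0 with 0 called in limma, 3 efferocytosis genes passing adjusted over the list alone. Camera with the mouse block, run at the preset correlation only, added neutrophil (higher, adjusted p = 0.039) and stromal genes (lower, 0.025).

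The mouse block gave 20 genes for the KLA response between genotypes, 9 of the 11 among them, and ended the call of Acaca (adjusted p = 0.094) and that of a gene outside the naming rule, while Srebf1 was called with it (0.012). edgeR called 14 and DESeq2 49 (11 higher, 38 lower). The count was 30 without LXR-positive KLA 2, 5 without LXR-positive vehicle 3, DKO vehicle 1 or 2 or DKO KLA 1, and 6 without LXR-positive vehicle 1 or 2 or DKO KLA 2 or 3. Fdft1 lost its call without any library but LXR-positive KLA 2 (adjusted p 0.057 to 0.16), Fads2 (0.12 to 0.19) and Acaca (0.061 to 0.13) without any but that and DKO vehicle 3, and Abcg1 without any LXR-positive vehicle library, DKO vehicle 1 or 2 or DKO KLA 1 or 3 (0.061 to 0.10). The call of Fads2 also ended with median-of-ratios rescaling, a pseudocount of 0.25 or 8, no filter and thinned reads (0.05002 to 0.065). Fdft1 overlaps Ctsb and Cyp51 overlaps Akap9 on the opposite strand, so reads of these genes cannot be told apart with certainty.

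**Figure D2:**
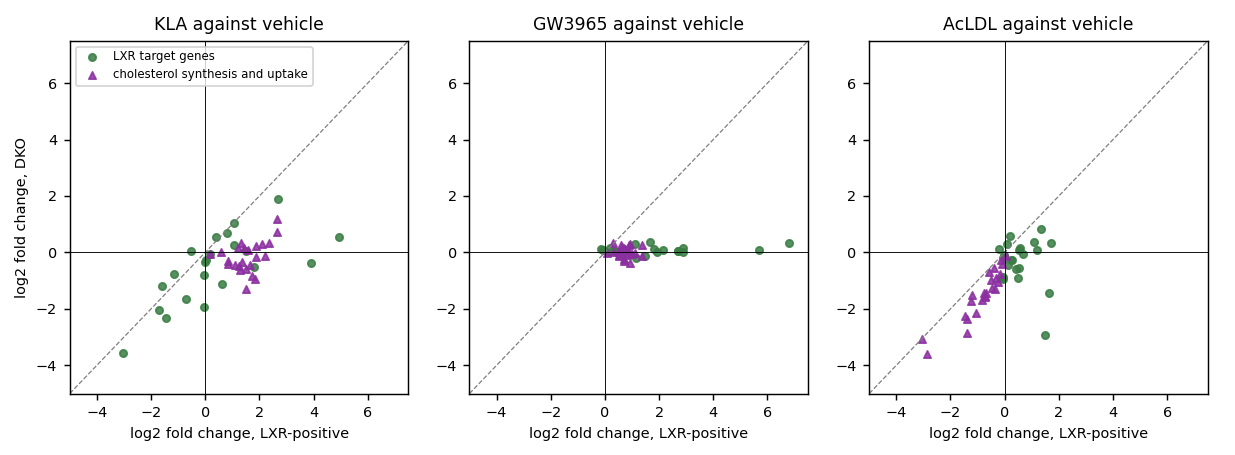
Log2 fold changes of LXR target genes and cholesterol genes against vehicle, DKO on the vertical and LXR-positive on the horizontal axis, a panel per treatment and a point per gene. With GW3965 LXR targets had a median of 1.31 in LXR-positive and 0.08 in DKO cells, and with KLA cholesterol genes had medians of 1.51 and -0.15, while with AcLDL cholesterol genes lay below 0 in both (-0.70 and -1.43).

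With vehicle, the desaturase Scd2 and the immunoglobulin transcripts Ighg2b and Igkc were higher in DKO macrophages. Scd2 stood at 1869 ± 687 normalized counts in DKO and 238 ± 6.51 in LXR-positive vehicle libraries (log2 difference 2.91 ± 0.24 SE, limma adjusted p = 1.1e-04). Cyp51, lanosterol demethylase (1.20 ± 0.18), Srebf1 (0.91 ± 0.15), Abca1 (0.80 ± 0.10) and Abcg1 (0.60 ± 0.11) were higher as well, and Mylip was lower (-0.75 ± 0.12). Ighg2b and Igkc, antibody heavy and light chain constant regions, stood at 345 ± 134 and 494 ± 244 in DKO and at 0.259 ± 0.449 and 5.15 ± 4.74 in LXR-positive vehicle libraries. Cat, catalase (5732 ± 452 in LXR-positive and 2228 ± 331 in DKO libraries), Ide, insulin-degrading enzyme (675 ± 125 and 275 ± 18.3), and Plxdc2, a membrane receptor (1906 ± 179 and 220.2 ± 39.3), were lower in DKO libraries. Mid1, a ubiquitin ligase (2.25 ± 0.18), and Erdr1 (2.29 ± 0.34) were higher, and Wwc2 was lower (-0.85 ± 0.13). Of these, Scd2, Ighg2b, Cat, Plxdc2 and Mid1 kept the call in limma on the 6 vehicle libraries alone and with replicate numbers as a block, which no label pairs across genotypes. Both ended the calls of Igkc, Ide and Erdr1 (adjusted p = 0.056 each on the 6 libraries and 0.074 each with the block), Abca1 (0.064 and 0.23), Cyp51 (0.075 and 0.18), Wwc2 (0.097 and 0.26), Mylip (0.11 and 0.23), Srebf1 (0.21 and 0.33) and Abcg1 (0.23 and 0.30). Fitted with the KLA libraries in place of the GW3965 libraries, Abca1 (adjusted p = 0.0505), Cyp51 (0.082), Srebf1 (0.10), Mylip (0.14) and Abcg1 (0.26) lost the call, and with the AcLDL libraries Abcg1 (0.095) and Cyp51 (0.15) did. Thinned reads ended the calls of Abcg1 (0.078) and Wwc2 (0.094), and no filter that of Abcg1 (0.075).

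**Figure D3:**
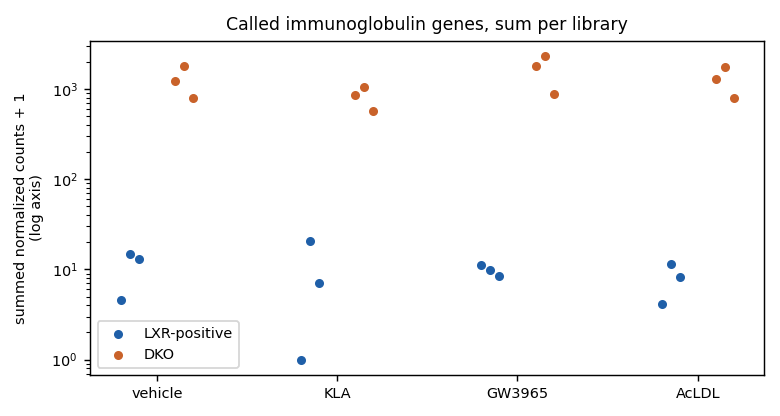
Sum of the normalized counts of 11 called immunoglobulin and J chain genes plus 1 (log axis) in each of the 24 libraries, by treatment and genotype, a point per library. The 12 DKO libraries lay between 571 and 2343, all above the 12 LXR-positive libraries at 0 to 19.5. The genes were chosen by their calls in the vehicle libraries, which are among those shown, and the 12 libraries of a genotype come from 3 mice.

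Among 24 cholesterol genes 5 were higher in DKO vehicle libraries (17 adjusted over the list alone; median 0.67, camera adjusted p = 4.8e-18, adjusted p = 0.15 with an estimated correlation). Fatty acid genes gave 2 of 15 (8 adjusted over the list alone; camera adjusted p = 1.8e-07, adjusted p = 0.15 with an estimated correlation), and LXR targets 4 higher and 1 lower of 22 (7 and 1; 0.0029, adjusted p = 0.15 with an estimated correlation). Beside these groups, camera called lists without a called gene in limma. Cell cycle genes were above 0 in 23 of 23 cases (median 1.04, camera adjusted p = 1.8e-06, adjusted p = 0.44 with an estimated correlation). Neutrophil precursor markers were above 0 in 11 of 11 (5 adjusted over the list alone; median 0.80, camera adjusted p = 1.8e-06, adjusted p = 0.15 with an estimated correlation). Stromal markers (median 1.88, camera adjusted p = 0.016, adjusted p = 0.44 with an estimated correlation) and mitochondrial and structural RNAs (0.32, 0.015, 0.44 with an estimated correlation) were also called higher. Interferon-stimulated genes (median -0.40, camera adjusted p = 3.2e-05, adjusted p = 0.47 with an estimated correlation), NRF2 targets (-0.33, 8.3e-05, 0.15 with an estimated correlation) and macrophage identity genes (-0.38, 0.046, 0.26 with an estimated correlation) were called lower. For interferon-stimulated genes, this difference, the negative GW3965 and AcLDL medians in LXR-positive cells and the positive differences of response all rest on the same LXR-positive vehicle libraries. A high level in those libraries alone would give all of these signs, so they do not count as separate results.

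In all, 51 of 16116 genes differed between the vehicle groups, 39 higher and 12 lower in DKO (76.5% higher), with Ide counted on 2 entries. The spread of this fit also came from the GW3965 libraries of the same mice, which are not independent of the vehicle libraries. With 3 mice per genotype, its p-values therefore overstate the evidence. The baseline list tests and the count of baseline calls near the targeted genes rest on the same fit. DESeq2 called 300 genes, 136 higher and 164 lower (45.3% higher), edgeR called 46, and limma on the 6 vehicle libraries alone 10 and with the block 11. Fitted with the KLA or AcLDL libraries the counts were 42 and 47, of which 31 and 37 were among the 51. The count was 29 without LXR-positive vehicle 1, 90 without LXR-positive vehicle 2, 26 without LXR-positive vehicle 3 and 20 without DKO vehicle 2. Among the genes named, calls ended without single libraries for Abcg1 (without any but DKO 3, adjusted p 0.054 to 0.20), Mylip (any but LXR-positive 2, 0.052 to 0.14), Wwc2 (any but LXR-positive 2, 0.052 to 0.096), Cyp51 (LXR-positive 1 or 3 or DKO 2, 0.068 to 0.085), Erdr1 (the same 3, 0.051 to 0.081), and Srebf1 (LXR-positive 3 or DKO 2 or 3, 0.092 to 0.13).

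The responses of LXR-positive macrophages to the 3 treatments were set side by side. GW3965 and AcLDL both raised 6 genes, Abcg1, Abca1 and Mylip among them. Independent lists of these lengths would share 0.0328 among 15782 genes, and 0 genes were lower in both. Another 3 genes went opposite ways, Insig1 and Fdps among them, higher with GW3965 and lower with AcLDL. KLA and GW3965 shared 22 higher genes against 6.13 for independent lists, and 8 genes went opposite ways. KLA and AcLDL shared 2 higher genes against 2.36, and 23 genes went opposite ways. All comparisons used the same 3 vehicle libraries, which cannot be split with 2 libraries on each side, so part of any excess may come from them. The covariance of log2 fold changes was 0.1005 for GW3965 and AcLDL (0.0928 in 20 simulations of unchanged groups), 0.0898 for KLA and GW3965 (0.0956) and 0.0292 for KLA and AcLDL (0.0894). The SDs over simulations were 0.0037, 0.0054 and 0.0051. Each simulated library was drawn independently, whereas real libraries of a mouse share deviations that cancel in treated minus vehicle. The simulated covariances are therefore too high as a reference and cannot decide whether responses were shared. With the mouse block the first pair shared 14 genes (12 higher, 2 lower in both), the second 25 (23 and 2) and the last 36 (14 and 22). The AcLDL list was longer with the block (247 against 36 genes), and no count for independent lists was computed for the blocked lists. The overlaps of the blocked lists therefore do not show sharing beyond list length. Without the block, the shared higher genes exceeded the count for independent lists for GW3965 and AcLDL (6 against 0.0328) and for KLA and GW3965 (22 against 6.13). How much of that excess came from the shared vehicle libraries was not settled.

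Of the genes that changed in LXR-positive cells, those whose response was also smaller in DKO cells by the interaction test numbered 18 of 43 for GW3965 (17 higher, 1 lower), 3 of 36 for AcLDL (2 higher, 1 lower) and 9 of 4566 for KLA (9 higher). The authors' deposited tables called a difference of response for 39 genes with GW3965 (5 higher, 34 lower in DKO), 54 with KLA (8 and 46) and 11 with AcLDL (3 and 8). Of these, 18, 11 and 3 were also called by limma here, all in the same direction as in the authors' deposited tables.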

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

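The tests of starting level and of sequencing depth for the cholesterol pattern were chosen only after the result was seen, as were the counts over whole mice. The prediction of the cell cycle test was written before that test was run. Its gene list was fixed before the data were examined, but the test was not. Every value in this part was raised by 1 criterion, a tested difference between the genotypes in the response to the same treatment (limma interaction, DKO minus LXR-positive, log2 scale). Groups of 3 are too small for a search for single libraries far from the rest.

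With KLA the values were -5.32 for Mrps36-ps1, -4.88 for Fads2, -4.39 for Scd2, -2.80 for Cyp51, -2.58 for Idi1, -2.32 for Fdps, -2.05 for Fdft1, -2.04 for Utp14b, -1.90 for Abcg1, -1.71 for Hmgcs1 and -1.35 for Acaca. Mrps36-ps1, a pseudogene, had 0 reads in LXR-positive vehicle libraries and was at least 13.4-fold higher with KLA there, so its fitted value depends on the pseudocount. All called genes are listed, so Mrps36-ps1, Utp14b and Hmgcs1, which the naming rule does not cover, were chosen after their values were seen. Hmgcs1 lost its call without any library but LXR-positive KLA 2 (adjusted p 0.071 to 0.17) and with a pseudocount of 0.25 (0.0505). Utp14b, which shares 244 exon bases with Acsl3 on the same strand, lost it without LXR-positive vehicle 1 or 3, DKO vehicle 1 or 2 or DKO KLA 1 or 2 (0.056 to 0.072) and with the mouse block (0.082). In LXR-positive cells Abcg1 stayed near its vehicle level (1929 ± 94.6 and 1918 ± 526 normalized counts), and in DKO cells it went from 2945 ± 429 to 770.4 ± 133 (SD, n = 3).

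With GW3965 the values were -6.48 for Scd1, -5.59 for Scd2, -5.02 for Zfp708, -3.68 for Fads2, -2.86 for Fasn, -2.74 for Srebf1, -2.67 for Abcg1, -2.08 for Utp14b, -2.05 for Abca1, -1.69 for Pank1, -1.68 for Mylip, -1.61 for Acsl4, -1.52 for Insig1, -1.51 for Acaca, -1.39 for Gramd1b, -1.35 for Arl4c, -1.30 for Eepd1, -1.06 for AB124611 and 5.32 for Gm17383. Zfp708 had 0 reads in DKO GW3965 libraries (at least 8.27-fold lower than with vehicle) and Gm17383 had 0 in LXR-positive GW3965 libraries (at least 2.15-fold lower), so both fitted values depend on the pseudocount. Zfp708, Utp14b, Pank1, Acsl4, Acaca, Gramd1b, Arl4c, Eepd1, AB124611 and Gm17383 were chosen after their values were seen. Of these, calls ended for Zfp708 without any GW3965 library or DKO vehicle 1 or 2 (adjusted p 0.058 to 0.11), with the mouse block (0.105), a pseudocount of 8 (0.33) and thinned reads (0.061), and for Gramd1b without any LXR-positive vehicle library, LXR-positive GW3965 1 or 3, DKO vehicle 1 or 2 or DKO GW3965 1 or 3 (0.088 to 0.13), with the block (0.054) and with thinned reads (0.0505). They ended for Pank1 without LXR-positive vehicle 3, any LXR-positive GW3965 library, DKO vehicle 1 or 2 or DKO GW3965 1 or 3 (0.053 to 0.095), for Eepd1 without LXR-positive vehicle 2 or 3, LXR-positive GW3965 1 or 3, DKO vehicle 2 or 3 or any DKO GW3965 library (0.053 to 0.10), and for Gm17383 with a pseudocount of 8 (0.051).

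With AcLDL the values were -4.43 for Scd2, -1.40 for Abcg1, -1.08 for Abca1 and 5.74 for Pole2. Pole2, chosen after its value was seen, had 0 reads in LXR-positive AcLDL libraries (at least 7.30-fold lower than with vehicle).

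Regroupings of single libraries between genotypes gave as many calls as the real 11 (KLA), 19 (GW3965) and 4 (AcLDL) in 8, 7 and 6 of 100 draws, the real one included. The rule written before these draws counted a share of 0.05 or more toward chance, and each of these shares met it. The other draws as large parted the libraries of at least 4 mice, and the highest called 1614, 2438 and 2424 genes, several times the real counts, which points to a structure of the samples: with mice parted, differences between mice and genotypes enter the tested difference of response. These draws are therefore no measure of chance for the real split, which parts no mouse. That reading departs from the rule and was made after the counts were seen. Among draws that parted fewer than 4, the highest counts were 3, 12 and 2. Of the 10 splits that part no mouse, 1 reached each real count, and the highest others called 1, 2 and 1 genes; 10 splits are too few for a share under 0.05.

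The pattern weighed here is the rise of cholesterol synthesis genes after KLA in LXR-positive and not in DKO macrophages (median difference -1.71 over 24 genes). A higher starting level in DKO cells alone is argued against, because between KLA-treated libraries the median difference was -1.02, with 24 of 24 genes lower in DKO, while with vehicle it was 0.67. Depth is argued against by reads thinned to the lowest total, which left a median of -1.70, and cell cycle level by its use as a covariate, which left -1.82 with 22 of 24 genes passing adjusted over the list alone. A candidate explanation, as a hypothesis only, is that the sterol gene response to KLA depends on LXR; it was found and tested on the same 6 mice. Other differences between the 3 DKO mice and the 3 others, such as culture or strain background, were not tested and stay open.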

How the results depend on the processing

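The count tests (edgeR, also with the block, and DESeq2), the thinned reads and the overlaps with the block or edgeR were chosen only after the data were seen. For the 240 values of named genes, 4355 of 4665 alternatives kept their side of the threshold, 287 lost the call and 23 gained it. Direction was compared only where a gene was called in the main fit or in the alternative, and 0 of those reversed. Where a count moved, the cause was not tested. A 2-fold threshold gave 2091 genes for KLA in LXR-positive and 1846 in DKO cells, and overlaps of 3 (GW3965 and AcLDL) and 1 (KLA and AcLDL). The replicate block by mouse gave 20 genes for the KLA response between genotypes, 0 for GW3965 in DKO cells, 247 and 38 for AcLDL in LXR-positive and DKO cells, and overlaps of 14 and 36. It moved no other count of genes over 1.5 times; of the 240 named values 14 lost the call with it and 3 gained it. Across genotypes, where no label pairs the replicate numbers, it gave 11 baseline genes. edgeR gave 20 genes for AcLDL in LXR-positive cells, 0 for GW3965 in DKO cells and an overlap of 1 (KLA and AcLDL). With edgeR and the replicate block the counts were 21 (KLA between genotypes), 0 (GW3965 in DKO), 157 and 38 (AcLDL in LXR-positive and DKO) and 1 (AcLDL between genotypes). DESeq2 gave 49, 55 and 13 genes for the KLA, GW3965 and AcLDL responses between genotypes, 87 and 26 for GW3965 and 285 and 82 for AcLDL in LXR-positive and DKO cells, and 300 at baseline. For GW3965 in DKO cells quantile normalization gave 3, no filter 5, and the stricter filter, pseudocount 8, only the groups compared and thinned reads 0 each (limma, 940 at an unadjusted p under 0.05 and 1 call as reported). Only the groups compared gave 10 baseline genes. Counting genes called in LXR-positive and not in DKO cells, with no test of the difference, gave 1601 (KLA), 43 (GW3965) and 25 (AcLDL), against 9, 18 and 3 by interaction.

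Lists called in camera, 11 and 11 (KLA in LXR-positive and DKO), 8 (KLA between genotypes), 4, 0 and 4 (GW3965, same order), 9, 8 and 5 (AcLDL) and 11 (baseline), became 2, 2 and 4 (KLA), 2 and 3, and 3 between genotypes (AcLDL), and 0 (baseline) with an estimated correlation. fry called 17 and 4 (KLA in LXR-positive cells and between genotypes), 3 and 3 (AcLDL in DKO cells and between genotypes) and 5 (baseline). The replicate block gave 8, 6 and 10 for GW3965 and 8 for AcLDL between genotypes.

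Leaving out each library in turn gave 3623 to 4453 and 2716 to 3502 genes for KLA in LXR-positive and DKO cells and 5 to 30 between genotypes, 36 to 46, 0 to 2 and 13 to 22 for GW3965, 10 to 33, 16 to 26 and 1 to 5 for AcLDL, and 20 to 90 at baseline. Depth limits low genes most in the LXR-positive GW3965 libraries, where the shallowest held 6448579 reads.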

Other observations

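The strain variant test, its alternatives and the depth tests were chosen only after the results were seen. The prediction of the plasma cell test was written before that test was run. Neither its gene list nor the test was among those fixed before the data were examined. Further lists were tested with KLA. NRF2 targets rose in 4 of 11 cases in each genotype (4 in each adjusted over the list alone; camera adjusted p = 0.024 and 0.027, adjusted p = 0.37 and 0.40 with an estimated correlation). Among them were Slc7a11, the cystine transporter (3.13 ± 0.50 SE and 2.12 ± 0.50), and Hmox1, heme oxygenase (1.68 ± 0.15 and 1.93 ± 0.15). Genes of the unfolded protein and amino acid response rose in 6 and fell in 1 of 13 cases in LXR-positive cells and rose in 5 and fell in 1 in DKO cells (camera adjusted p = 0.065 and 0.13), with Hspa5, the chaperone BiP, rising by 1.11 ± 0.16 and 1.05 ± 0.16. Lysosomal genes went both ways, 4 higher and 6 lower of 18 in LXR-positive and 3 and 7 in DKO cells (camera adjusted p = 0.18 and 0.027, the second adjusted p = 0.40 with an estimated correlation). Lgmn, the protease legumain, fell by 1.85 and 1.27. Macrophage identity genes rose in 4 and fell in 2 of 11 cases in LXR-positive cells and rose in 6 and fell in 2 in DKO cells (camera adjusted p = 0.52 and 0.089), with Adgre1, which encodes F4/80, rising from 27130.4 ± 2114 to 62685 ± 4955 normalized counts in LXR-positive cells.

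Markers of other cell types were also tested with KLA. Osteoclast markers had 1 higher and 2 lower of 5 in both genotypes (camera adjusted p = 0.44 and 0.30), with Acp5, tartrate-resistant acid phosphatase, rising (3.56 ± 0.26 and 3.54 ± 0.26) and Nfatc1 falling by 1.02 and 0.68. Dendritic cell markers had 1 higher and 1 lower of 8 in both (0.78 and 0.98). In LXR-positive cells lymphocyte markers had 1 lower of 3 (0.32), mast cell, basophil and eosinophil markers 1 lower of 3 (0.27), stromal markers 1 higher of 10 (0.41), and erythroid and megakaryocyte markers 0 of 3 called in limma (0.66). These were Cd3d (-1.18 ± 0.37), which lost its call without vehicle 1 or 3 or KLA 2 (adjusted p 0.074 to 0.10), Prg2 (-1.52 ± 0.45), without vehicle 2 or 3 or KLA 1 or 3 (0.064 to 0.10), and Pdgfrb (2.36 ± 0.66), without vehicle 2 or 3 or KLA 1 (0.052 to 0.072). Quantile normalization and only the 6 libraries compared also ended the calls of Cd3d (0.076 and 0.13) and Prg2 (0.0503 and 0.12), and no filter, DESeq2 and thinned reads that of Cd3d (0.052 to 0.0897). In DKO cells the 4 lists had 0 called in limma (camera adjusted p = 0.85, 0.22, 0.87 and 0.71). Mitochondrial and structural RNAs had 0 of 16 called in limma in LXR-positive and 1 lower in DKO cells (0.18 and 0.14). With AcLDL camera called lysosomal genes higher in LXR-positive cells (adjusted p = 0.043, adjusted p = 0.49 with an estimated correlation) and erythroid and megakaryocyte markers higher in DKO cells (0.044, adjusted p = 0.26 with an estimated correlation). It called neutrophil markers lower in LXR-positive cells with the mouse block (0.026) and not without it (0.051). At baseline erythroid and megakaryocyte markers were called higher in DKO cells (median 0.98, 0.036, adjusted p = 0.26 with an estimated correlation).

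Of 21 tested immunoglobulin and J chain genes, a set chosen after the values were seen, 21 had higher levels in DKO vehicle macrophages and 11 were called. With replicate numbers as a block, which no label pairs across genotypes, 3 stayed called, and so did 4 with only the 6 vehicle libraries, 6 without DKO vehicle 2 and 9 with a pseudocount of 8. In the fits with the KLA or the AcLDL libraries 12 of 17 tested were called. Depth is argued against: with reads thinned to the lowest total, 6 of the 11 stayed called, and the lowest DKO sum was 277 against a highest LXR-positive sum of 10.7. RNA from plasma cells, the antibody-secreting cells, is a candidate source that stays open. The 6 genes of a 14-gene plasma cell list that lay under 10 in LXR-positive vehicle cells summed to more than the highest LXR-positive library (21.4) in 6 of 12 DKO libraries (means 22.2 and 10.9). Choosing genes that were low in LXR-positive vehicle cells favours a higher DKO sum, and the 12 libraries come from 3 mice. The list's other genes were not called at baseline (limma adjusted p from 0.56 for Sdc1 to 0.92 for Xbp1). Over 12 libraries Mzb1 averaged 1.59 in DKO and 0 in LXR-positive cells, Pou2af1 8.29 and 0.719, Cd79a 6.62 and 2.11, and Derl3 0.396 and 0, while Tnfrsf17 (2.36 and 3.92) and Fkbp11 (2.995 and 4.15) were lower in DKO cells. No sort that would remove such cells is given in the labels, and a biological effect of genotype was not tested.

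Baseline calls made up 5 of 615 tested genes within 20 Mb of Nr1h3 or Nr1h2 (0.813%) and 45 of 15324 elsewhere (0.294%; odds ratio 2.78, Fisher's exact test, two-sided, p = 0.0428). The 5, named because they were called and so chosen after their values were seen, were Rbm45 (-0.68), Tspan18 (1.30), Api5 (-0.56), Cat (-1.37) and Zfp30 (1.69), each with the same sign in all 4 treatments. The 4 treatments used cells of the same mice, so they are not independent. The excess rests on few calls. Fisher's exact test takes genes as independent, but Tspan18, Api5 and Cat lie between 93201760 and 103485160 on chromosome 2. Neighbouring genes of the same mice may differ together, so its p-values here are descriptive only. In 11 other fits the odds ratio was 1.47 to 5.55, with Fisher's exact test p = 0.024 without DKO vehicle 1 and 0.065 to 0.65 in the other 10. With replicate numbers as a block, which no label pairs across genotypes, 4 of the 5 were not called (adjusted p = 0.14 to 0.34) and Cat was (0.043), and without LXR-positive vehicle 1 or 3 or DKO vehicle 2 or 3, Rbm45, Tspan18 and Api5 were not (0.066 to 0.22), nor Rbm45 without LXR-positive vehicle 2 (0.057) or Api5 without DKO vehicle 1 (0.089). On the vehicle libraries alone Cat stayed called (limma adjusted p = 0.015) and the other 4 did not (0.0565 to 0.21). Fitted with the KLA libraries, Api5 (0.075), Rbm45 (0.077) and Zfp30 (0.087) lost the call, and with the AcLDL libraries Rbm45 did (0.071). With thinned reads Tspan18, Api5 and Cat stayed called and all 5 kept at least 50% of their log2 difference, which argues against depth for these 3, while Rbm45 (0.0765) and Zfp30 (0.11) lost the call and the excess had an odds ratio of 2.12 (Fisher's exact test p = 0.18). Strain variants carried along with the targeted genes may account for some of these calls, as a hypothesis that most of these fits did not bear out. The labels give C57BL/6J for all mice and no history of backcrossing, so this stays open.

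For comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split, 1 of 10 to reach its own count in each, called 4566 genes for KLA in LXR-positive cells (highest other 3), 4016 in DKO cells (0), 43 for GW3965 in LXR-positive cells (1), 1 in DKO cells (0), 36 for AcLDL in LXR-positive cells (3, or 2 among splits that part as many pairs), 20 in DKO cells (2) and 51 at baseline (3).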
